A study of Bos taurus with 7 samples.

How the data were processed

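Luteal tissue of day 4 (3 libraries) and day 6 (4 libraries) was compared. Per the labels, cycles were synchronised with a progesterone device for 7 days, 25 mg of PGF2α and 86 mcg of gonadotropin-releasing hormone, and ovulation was checked by ultrasound on day 2. Per the labels, RNA was isolated with a miRCURY kit, libraries were made with the Illumina Stranded mRNA Prep kit, and single reads of 100 nt were obtained on an Illumina NextSeq instrument. Proteomics named in the series description was not analysed here.

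The deposited data used here are 1 table of the authors with 19539 entries, each with group means and test results, and no values or counts per library. The sequencing depth of each library is therefore unknown, and no counting interval or detection floor was computed. The submitters' processing notes name FastQC, DESeq2 and the genome build ARS-UCD1.2, without versions. The read counting tool and the annotation are not given in the sources used here. The authors' mean values per day are in TPM, a length-scaled share of the transcripts, a unit read from the values, since each deposited column of means sums to 999999. The authors' deposited log2 fold change is the log2 ratio of both mean TPM after adding 1, which held for all 19539 entries within a tolerance of 1e-06. The deposited score of each entry is the Wald statistic of the authors' test, and a log2 standard error stands beside it. The authors' p-value equals the two-sided normal p of that score in 19485 entries, and their adjusted p-value is the Benjamini-Hochberg value over these. For 54 other entries the deposited p-value is 1, and they were left out of all tests. The authors' identifiers are gene symbols, or transcript identifiers in 3559 entries, and 55 symbols stand on more than 1 entry.

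The log2 fold change used here, day 6 over day 4, is the deposited score times its standard error. The deposited log2 ratio was not used for sizes, since adding 1 shrinks it for genes of low TPM. Of the called genes, 1514 have a deposited value under 1 in size, and 570 of these reach 1 as a Wald fold change. Some of the 570 do so through scaling instead, since Wald fold changes lay 0.21 above the log2 ratio of mean TPM. LYVE1 (29.4 to 56.2 TPM), for one, has 0.91 deposited, 1.16 as a Wald fold change and 0.94 with that shift taken off. Calls are the authors' adjusted p under 0.05. No test across libraries was run here. Intervals of a gene are 95% Wald intervals. No coordinates are given, since the annotation at hand, ARS-UCD2.0, is not the authors' build. It served to match symbols by synonym and to find overlapping mitochondrial genes.

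Before the data were examined, 38 gene lists with 955 genes, a panel of 24 genes and a rule for naming genes were fixed. Of these genes 911 were matched, and 44 were not. The rule takes the 8 called genes with the largest rise and the 8 with the largest fall, the panel, and the 4 members of each list with the smallest adjusted p. Its minimum expression, which holds for the largest changes only and not for the panel or the lists, was set for counts and became a mean of 2 TPM, and its demand that groups not overlap could not be applied without library values. Not every gene the rule selects is given in the text. Genes outside the rule are given as named after their values were seen, or as the single member of a list called in the other direction. The mitochondrially encoded and ribosomal protein lists were added after the data were examined.

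The plan fixed beforehand foresaw no test for a table that holds only the authors' comparison. The test of the lists was therefore chosen after the table was seen: cameraPR of limma 3.58.1 (R 4.3.3) on the deposited score, at a preset correlation of 0.01 between genes, for lists of at least 5 tested members, with Benjamini-Hochberg adjustment over the fixed lists and again over all lists for the added ones. It compares the mean score of a list with that of all other genes. A list median has a bootstrap interval over its genes (10000 draws), and was set beside 10000 random lists matched on 10 bins of mean TPM. Genes are not independent replicates, so these intervals cover the choice of genes and not the animals. Alternatives were the TPM scale, the TPM scale without the mitochondrially encoded genes, centring on the median gene of at least 1 TPM, a minimum mean of 1 TPM, an adjusted p under 0.01, a Wald test against a fold of 1.5, a t distribution with 5 degrees of freedom, and for the lists preset correlations of 0.05 and 0.1, ranks, the TPM scale and the minimum of 1 TPM.

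The procedure was tested on simulated data built on the deposited standard errors. Each simulation of genes changed 200 of 19485. The authors' test called 2823, so its adjusted cut-off is less strict and its recovery may differ from the simulated one. Of 200 genes given a true log2 change of 1 it recovered 35%, and 58.3% of those of at least 5 TPM, with 1.41% false among the calls. At a log2 change of 2 it recovered 70%, with 6.67% false among the calls, above the 5% aimed at, and at 0.5 it recovered 3%. Of 40 simulated lists shifted by 0.7 in the score it called 75%, and 0 of 380 lists without a shift. Scores were drawn independently for each gene, so false calls from genes that vary together were not tested. The noise was normal with a known spread, so the effect of the small number of libraries was not tested either. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.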

Results

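Whole luteal tissue was sampled on day 4 (3 libraries) and day 6 (4 libraries) of the estrous cycle. All cows had been synchronised alike with a progesterone device, a prostaglandin and gonadotropin-releasing hormone, and the labels otherwise give them as untreated. Its messenger RNA was sequenced with stranded single reads of 100 nt. The corpus luteum is the gland that forms from the ovulated follicle and secretes progesterone. Early in the cycle the bovine gland does not regress after prostaglandin F2α (PGF2α), the uterine signal that ends luteal function. The study's title names the acquisition of this capacity, with luteal apoptosis and immune mechanisms, as its subject. Per the labels, day 4 glands were collected after slaughter and glands taken after day 6 by colpotomy, removal through the vaginal wall. The route for day 6 itself is left open, so a change of collection route may coincide with the change of day. The labels also do not state that each library came from a different cow, and p-values then measure the spread between these samples.

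Every mean TPM (a length-scaled share of transcripts), standard error and adjusted p-value of a gene is from the authors' deposited table. It holds 1 mean per day and 1 Wald test per gene, so how many libraries show a direction is not known. Counts per library are not in it, so the sequencing depth behind each value is unknown. Log2 fold changes are day 6 over day 4, taken as the deposited Wald statistic times its standard error. Values of a gene are given as mean TPM on day 4 and on day 6, then log2 fold change ± the authors' standard error. A gene is called when its adjusted p in the authors' deposited table lies under 0.05. Intervals beside a list median are 95% bootstrap intervals over genes and do not cover the spread between libraries.

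Among the largest rises of called genes averaging at least 2 TPM in the authors' deposited table was that of INSRR, an insulin receptor relative (1.59 to 18.6 TPM, log2 3.73 ± 0.38, adjusted p = 2.01e-19). CRABP1, a retinoic acid binding protein (0.936 to 10.04 TPM, log2 3.72 ± 0.69), and SLC6A6, the taurine transporter (6.65 to 53.7 TPM, log2 3.18 ± 0.43), also rose there. RANBP3L (6.06 to 54.9 TPM, log2 3.38 ± 0.76), MASP1, a protease of the lectin pathway of complement (12.4 to 105 TPM, log2 3.36 ± 1.16, adjusted p = 0.0328), and the mitochondrially encoded ND5 and ND6 were also among the 8 largest rises in the authors' deposited table. Among the largest falls, SFRP4, a secreted WNT antagonist, was nearly lost on day 6 (109 to 0.125 TPM, log2 -9.57 ± 1.44, adjusted p = 1.01e-08), as was PENK, the enkephalin precursor (72 to 0.116 TPM, log2 -9.08 ± 1.59, adjusted p = 1.5e-06), in the authors' deposited table. COCH (42.3 to 0.146 TPM, log2 -8.22 ± 1.34), CBLN2 (5.28 to 0.00399 TPM, log2 -10.18 ± 1.76) and the ovarian signalling ligand WNT4 (4.9 to 0.0148 TPM, log2 -8.12 ± 0.81, adjusted p = 4.46e-20) fell in the authors' deposited table. LRRN1 (9.78 to 0.0717 TPM, log2 -6.92 ± 1.15), PPP1R1B (7.72 to 0.136 TPM, log2 -6.30 ± 0.82) and the plasma cell gene MZB1 (11.9 to 0.151 TPM, log2 -6.12 ± 1.16) complete the 8 largest falls of called genes averaging at least 2 TPM there.

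Of 19485 entries tested in the authors' deposited table, 2823 were called, 803 higher and 2020 lower on day 6. Of those averaging at least 20 TPM, 359 were higher and 448 lower, and of those under 1 TPM, 36 were higher and 404 lower. At a mean of at least 100 TPM, 63 were higher and 172 lower. The split depended on scaling: the Wald fold changes lay 0.21 above the log2 ratio of the deposited mean TPM (median of 10599 entries averaging at least 5 TPM). With that shift taken off, called the TPM scale here, 299 were higher and 3829 lower (7.24% higher, against 28.4%). On the TPM scale without the mitochondrially encoded genes 1848 were higher and 1595 lower (53.7% higher). Directions of called genes given here hold on these scales. Calls lost on the TPM scale include those of API5, ATF6, ERAP1, FOXL2, GSTM3, HSP90AA1, HSPA9, ITPR2, PMVK, SEL1L, SOAT1, TAPBP and TREM1. The calls of ATF4, EGFL7, FAS, GATA2, GYPC, HSPB8 and NKG7 were lost on the TPM scale without the mitochondrially encoded genes. With a t distribution of 5 degrees of freedom in place of the normal, 0 were called, with 3133 at an unadjusted p under 0.05.

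Gene lists fixed before the data were examined were compared with all other genes by cameraPR at a preset correlation of 0.01 between genes. It called 17 of the 38 lists, 7 up and 10 down. Some lists share members, so their calls are not independent: 10 of 21 fibroblast genes, 7 of 37 matrix genes and 5 of 31 complement genes also stand on another list. The correlation cannot be estimated without library values. At a preset correlation of 0.05 there were 15 calls and at 0.1 there were 2, immediate early genes and pericytes with smooth muscle. Among the called lists the median standard error most exceeded that of random lists matched on expression for cholesterol synthesis (0.68 against 0.25), cell cycle (0.53 against 0.23), fibroblasts (0.42 against 0.24), progesterone synthesis (0.41 against 0.24) and interferon-stimulated genes (0.45 against 0.28). The spread between libraries was thus wide for these genes. How far they vary together between libraries cannot be estimated. All 40 cell cycle fold changes nevertheless lay between -0.01 and 0.96, beside a median standard error of 0.53. Those of cholesterol synthesis ran from -0.23 to 1.51, with a median of 1.27. Independent errors of that size would scatter more widely, which argues for errors shared within both lists. The preset correlation of 0.01 would then be too low for them and their cameraPR p-values too small. Fold changes of the other lists named here ranged more widely.

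**Figure D1:**
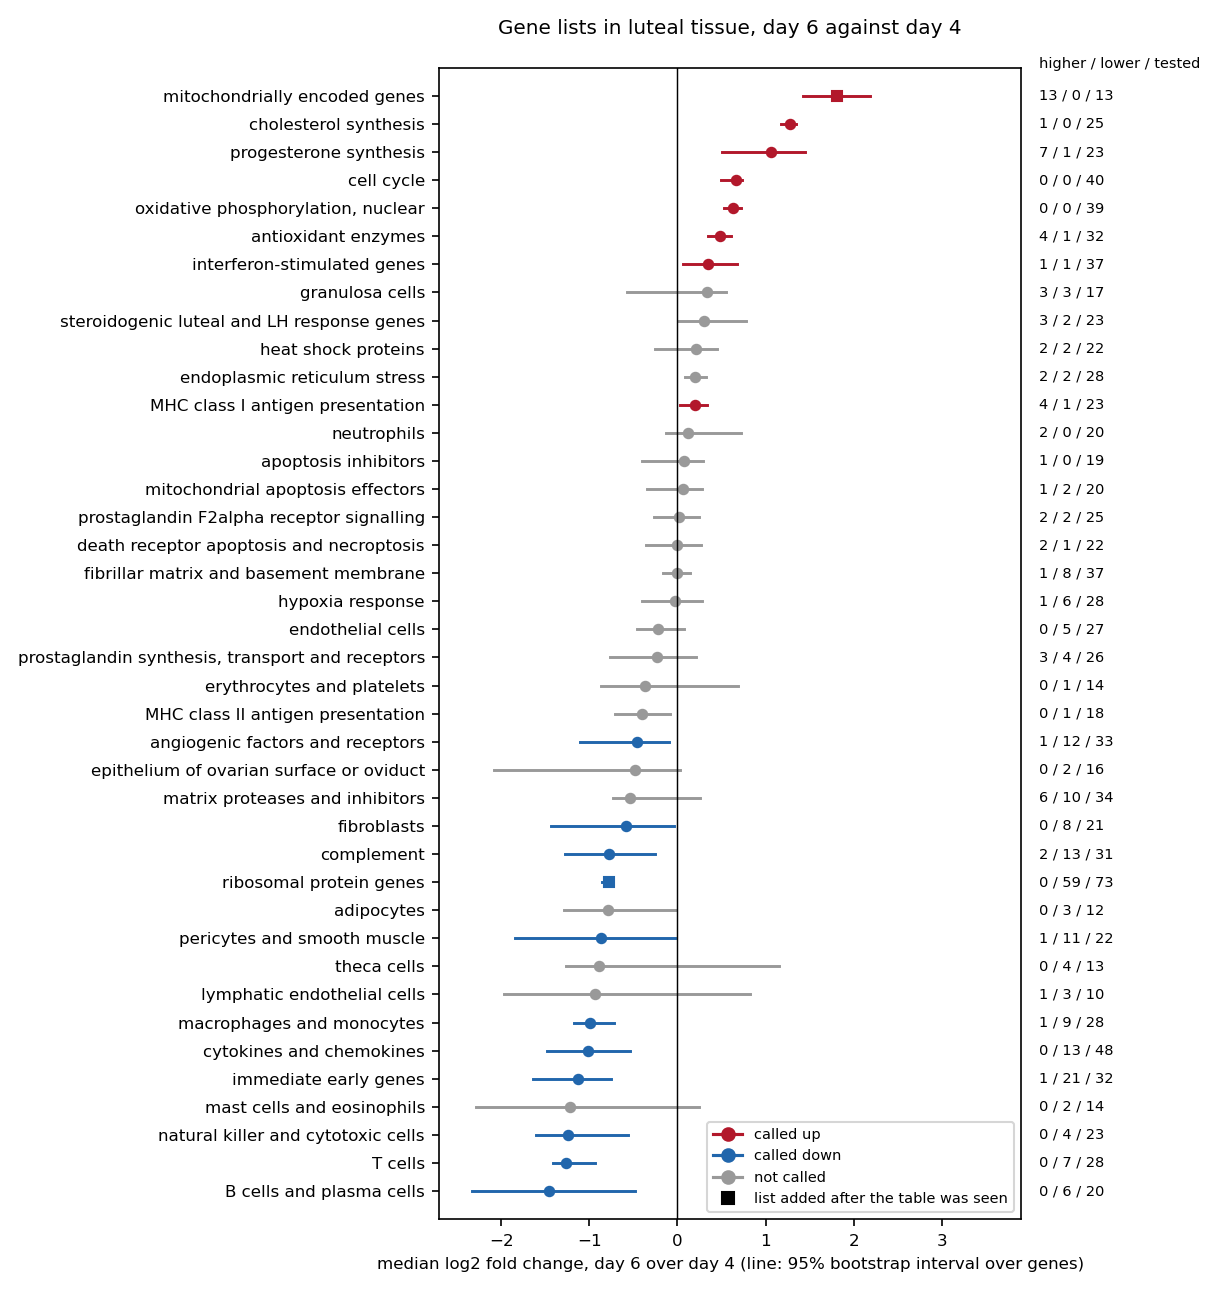
Median log2 fold change (day 6 over day 4) of each gene list with its 95% bootstrap interval over genes, coloured by the cameraPR call at a preset correlation of 0.01, and at the right the genes called higher, called lower and tested. Medians run from -1.46 for B cells and plasma cells to 1.81 for mitochondrially encoded genes, and those near 0 change sign with the scaling.

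Genes of progesterone synthesis rose as a group. STAR, which carries cholesterol into mitochondria and limits the rate of steroid synthesis, rose in the authors' deposited table (588 to 2504 TPM, log2 2.32 ± 0.74, adjusted p = 0.0189). STARD4, a cytosolic cholesterol carrier (8.1 to 16 TPM, log2 1.22 ± 0.25, adjusted p = 7.54e-05), LIPE, the hormone-sensitive lipase (7.54 to 15.9 TPM, log2 1.30 ± 0.41), and SOAT1, which esterifies cholesterol (25.2 to 44.9 TPM, log2 1.06 ± 0.36), also rose in the authors' deposited table. Named after their values were seen, the lipoprotein receptor SCARB1 (817 to 2912 TPM, log2 2.09 ± 0.75, adjusted p = 0.0394) and the ferredoxin reductase FDXR (118 to 301 TPM, log2 1.57 ± 0.56) rose there and NPC2, a lysosomal cholesterol carrier, fell (97.2 to 61.5 TPM, log2 -0.45 ± 0.16). Enzymes further along had higher means on day 6 with wide errors in the authors' deposited table and were not called. CYP11A1, which cleaves the cholesterol side chain, stood at 1316 to 3454 TPM, log2 1.61 ± 1.03, adjusted p = 0.295 in the authors' deposited table. HSD3B1, which makes progesterone, stood at 1995 to 4624 TPM, log2 1.44 ± 1.01, adjusted p = 0.343 there. Of the list's genes 7 of 23 were higher and 1 lower, and 9 and 1 when adjusted over the list alone. Its median was 1.06 (0.50 to 1.44), with cameraPR adjusted p = 0.000594, or adjusted p = 0.0857 at the preset correlation of 0.1.

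Cholesterol synthesis genes rose as a list, 24 of 25 having a positive fold change. PMVK, of the mevalonate pathway, was called singly (11.9 to 22.6 TPM, log2 1.18 ± 0.43, adjusted p = 0.044 in the authors' deposited table). MVK (48.5 to 79.99 TPM, log2 0.94 ± 0.35, adjusted p = 0.0527), the transcription factor SREBF2 (57.4 to 87.1 TPM, log2 0.84 ± 0.36) and its escort SCAP (139 to 268 TPM, log2 1.18 ± 0.50) came next in the authors' deposited table and were not called. The list median was 1.27 (1.18 to 1.34), with cameraPR adjusted p = 7.6e-05, or adjusted p = 0.0609 at the preset correlation of 0.1. Adjusted over the list alone 0 were called by the authors' Wald test, with 6 higher and 0 lower at an unadjusted p under 0.05.

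Other luteal genes went both ways. ESR2, an estrogen receptor, fell in the authors' deposited table (5.18 to 0.474 TPM, log2 -3.26 ± 0.67, adjusted p = 6.74e-05), while IGF1R, the receptor of insulin-like growth factor (18.5 to 27.3 TPM, log2 0.78 ± 0.18), and PRLR, the prolactin receptor (0.311 to 1.33 TPM, log2 2.48 ± 0.81), rose. LHCGR, the receptor for luteinizing hormone, was not called (68.5 to 134 TPM, log2 1.27 ± 0.69, adjusted p = 0.209 in the authors' deposited table). Nor was OXT, the oxytocin precursor and among the most abundant transcripts (8052 to 10393 TPM, log2 0.56 ± 1.33, adjusted p = 0.83 in the authors' deposited table). Of the steroidogenic luteal and LH response genes 3 of 23 were higher and 2 lower, and 4 and 2 when adjusted over the list alone, with a median of 0.30 (0.01 to 0.78), with cameraPR adjusted p = 0.096. Granulosa markers split: GSTA1, a glutathione transferase, rose (1132 to 4221 TPM, log2 2.14 ± 0.55, adjusted p = 0.00213) and FOXL2 rose slightly (26 to 29.4 TPM, log2 0.40 ± 0.14) in the authors' deposited table. GATM (12.5 to 3.59 TPM, log2 -1.60 ± 0.49) and HSD17B1 (2.87 to 0.588 TPM, log2 -2.07 ± 0.68) fell there. Of the granulosa genes 3 of 17 were higher and 3 lower, and 3 and 4 when adjusted over the list alone, with a median of 0.34 (-0.57 to 0.55), with cameraPR adjusted p = 0.634, and a mean of 0.00. Theca markers called were lower, among them TCF21 (104 to 5.64 TPM, log2 -4.03 ± 0.64, adjusted p = 9.76e-08) and GLI1, a target of hedgehog signalling (3.34 to 0.373 TPM, log2 -2.96 ± 0.86), in the authors' deposited table. NR2F2 (161 to 75 TPM, log2 -0.89 ± 0.29) and HHIP (0.415 to 0.0107 TPM, log2 -5.11 ± 1.83) fell there too. Of the theca genes 0 of 13 were higher and 4 lower, and 1 and 4 when adjusted over the list alone, with a median of -0.89 (-1.26 to 1.15), with cameraPR adjusted p = 0.109.

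Mitochondrially encoded transcripts rose. ATP8, a subunit of ATP synthase, rose in the authors' deposited table (46477 to 141372 TPM, log2 1.81 ± 0.24, adjusted p = 1.75e-11), as did COX1, of cytochrome oxidase (9124 to 23300.3 TPM, log2 1.56 ± 0.17, adjusted p = 3.17e-16). ND4L (4745 to 18897 TPM, log2 2.19 ± 0.25), ND5 (389.6 to 4276 TPM, log2 3.65 ± 0.38, adjusted p = 2.34e-18) and ND6 (856 to 9248 TPM, log2 3.62 ± 0.50), of complex I, rose in the authors' deposited table. All 13 protein genes were called higher, with log2 fold changes from 1.11 to 3.65. They made up 10.3% of the authors' mean TPM on day 4 and 29.2% on day 6, of which ATP8 alone held 4.65% and 14.1%. This list was added after the data were examined, with a median of 1.81 (1.42 to 2.19), with cameraPR adjusted p = 1.57e-35, or adjusted p = 3.78e-18 at the preset correlation of 0.1. ND5 and ND6 overlap each other, as do ATP8, ATP6 and COX3 in turn, and ND4L and ND4, so their values are uncertain where shared reads were not resolved.

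**Figure D2:**
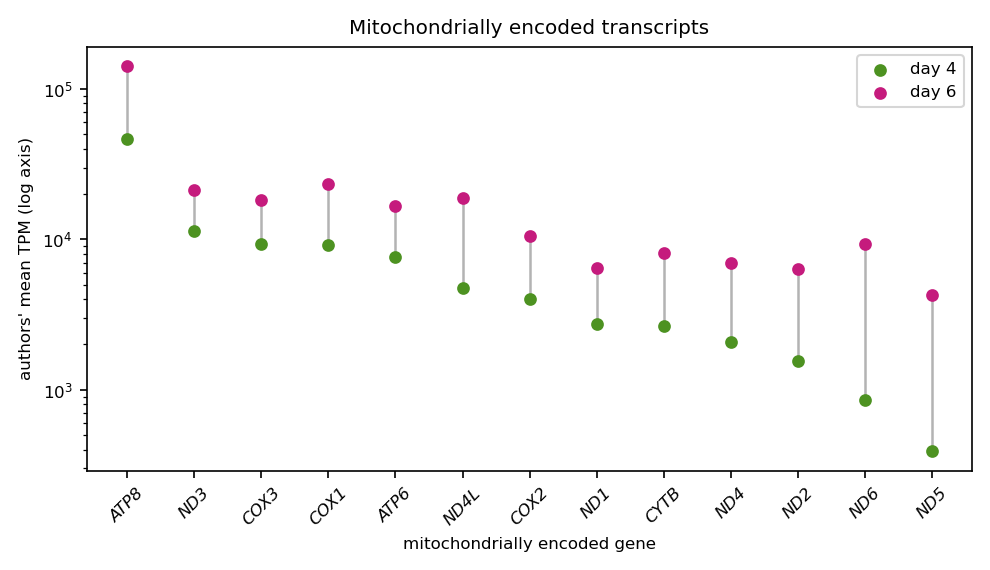
Authors' mean TPM (log axis) of the 13 mitochondrially encoded genes on day 4 and day 6, ordered by their day 4 level, with a line joining both means of a gene. Every gene lies higher on day 6, from ND3 (log2 fold change 1.11) to ND5 (3.65).

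Nuclear oxidative phosphorylation genes rose as a list, 38 of 39 having a positive fold change. SDHA, of complex II (133 to 202 TPM, log2 0.82 ± 0.34, adjusted p = 0.0866), NDUFB9 (124 to 179 TPM, log2 0.74 ± 0.31), NDUFS1 (36.6 to 57.7 TPM, log2 0.89 ± 0.39) and ATP5F1B (394 to 663 TPM, log2 0.98 ± 0.43) had the smallest adjusted p in the authors' deposited table and were not called. The median was 0.63 (0.53 to 0.72), with cameraPR adjusted p = 1.79e-06, or adjusted p = 0.06 at the preset correlation of 0.1. By the authors' Wald test 0 members were called, over all genes or adjusted over the list alone, with 10 higher and 1 lower at an unadjusted p under 0.05. The mitochondrially encoded median exceeded the nuclear one by 1.17 (0.75 to 1.58). Antioxidant enzymes rose as a list. CAT, the catalase gene (52.4 to 65.3 TPM, log2 0.54 ± 0.12, adjusted p = 0.000143), and SOD1, a superoxide dismutase (156 to 253 TPM, log2 0.92 ± 0.22, adjusted p = 0.0011), rose in the authors' deposited table, as did GSTM3 (250.4 to 411 TPM, log2 0.95 ± 0.31) and GSTA1. SELENOP, a selenium carrier, was the only member called lower (411 to 171 TPM, log2 -1.06 ± 0.37 in the authors' deposited table). Of these genes 4 of 32 were higher and 1 lower, and 10 and 1 when adjusted over the list alone, with a median of 0.48 (0.35 to 0.61), with cameraPR adjusted p = 0.000171, or adjusted p = 0.0857 at the preset correlation of 0.1.

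Cell cycle genes rose as a list and no member was called singly. FOXM1 (4.14 to 6.79 TPM, log2 0.95 ± 0.53, adjusted p = 0.225) and PRC1 (22.5 to 36.9 TPM, log2 0.87 ± 0.52) had the smallest adjusted p in the authors' deposited table. MKI67, the proliferation marker Ki-67, stood at 17.9 to 29.3 TPM, log2 0.96 ± 0.57, adjusted p = 0.257 and MYBL2 at 18 to 26.2 TPM, log2 0.76 ± 0.46 there. The median was 0.66 (0.50 to 0.74), with cameraPR adjusted p = 0.000337, or adjusted p = 0.116 at the preset correlation of 0.1, with 39 of 40 positive. By the authors' Wald test 0 were called over all genes or adjusted over the list alone, with 0 higher and 0 lower at an unadjusted p under 0.05.

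Prostaglandin genes changed singly. PTGDS, the prostaglandin D synthase, fell (499 to 38.1 TPM, log2 -3.55 ± 0.57, adjusted p = 9.88e-08), and PTGS2, the inducible cyclooxygenase, fell at a low level (1.11 to 0.254 TPM, log2 -1.93 ± 0.43, adjusted p = 0.000318) in the authors' deposited table. PTGER2, a receptor for prostaglandin E2, fell (1.37 to 0.488 TPM, log2 -1.28 ± 0.36), and SLCO2A1, the prostaglandin transporter, rose (10.1 to 15.4 TPM, log2 0.83 ± 0.22, adjusted p = 0.00382) in the authors' deposited table. PTGFR, the receptor of PGF2α, was abundant on both days and not called (673 to 1097 TPM, log2 0.95 ± 1.23, adjusted p = 0.654 in the authors' deposited table). Its 95% Wald interval of -1.46 to 3.36 leaves either direction open. HPGD, which inactivates prostaglandins, was not called (3.55 to 1.3 TPM, log2 -1.17 ± 0.50, adjusted p = 0.0945 in the authors' deposited table). Of the prostaglandin list 3 of 26 were higher and 4 lower, and 3 and 5 when adjusted over the list alone, with a median of -0.23 (-0.77 to 0.21), with cameraPR adjusted p = 0.537.

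Genes acting downstream of the PGF2α receptor showed no common direction. PLCB4, a phospholipase C (31 to 9.88 TPM, log2 -1.44 ± 0.36, adjusted p = 0.00137), and PRKCZ, an atypical protein kinase C (3.22 to 0.499 TPM, log2 -2.58 ± 0.69, adjusted p = 0.00343), fell in the authors' deposited table. ITPR2, a calcium channel of the endoplasmic reticulum, rose there (6.68 to 10.3 TPM, log2 0.88 ± 0.30). Of the list 2 of 25 were higher and 2 lower, and 2 and 2 when adjusted over the list alone. Its median was 0.02 (-0.27 to 0.25), with cameraPR adjusted p = 0.712, against a mean of -0.10 and a median of -0.20 on the TPM scale.

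Apoptosis genes, named in the study's title, were called in both directions. FAS, the receptor that starts death receptor signalling, fell in the authors' deposited table (4.77 to 2.35 TPM, log2 -0.75 ± 0.24, adjusted p = 0.0183). TNFRSF21 (7.83 to 12.2 TPM, log2 0.87 ± 0.23, adjusted p = 0.00316) and TNFRSF10D, a decoy receptor for TRAIL (47.2 to 95.3 TPM, log2 1.10 ± 0.33, adjusted p = 0.0109), rose in the authors' deposited table, where TNFRSF25 was not called (4.37 to 1.72 TPM, log2 -1.16 ± 0.46). BMF, a pro-apoptotic BH3-only gene (8.3 to 2.16 TPM, log2 -1.75 ± 0.44, adjusted p = 0.00161), and DFFB, a nuclease (5.27 to 1.9 TPM, log2 -1.26 ± 0.39), fell in the authors' deposited table. ENDOG, a mitochondrial nuclease, rose (10.4 to 15.7 TPM, log2 0.81 ± 0.21) and CASP9 was not called (7.23 to 3.38 TPM, log2 -0.89 ± 0.34) there. API5, an inhibitor, rose (26.2 to 34 TPM, log2 0.60 ± 0.21, adjusted p = 0.0365 in the authors' deposited table). BCL2, the founding inhibitor, was not called (5.58 to 1.99 TPM, log2 -1.29 ± 0.49, adjusted p = 0.0558), nor were BIRC3 (11.9 to 7.71 TPM, log2 -0.40 ± 0.16) and FAIM (7.08 to 3.73 TPM, log2 -0.71 ± 0.29), in the authors' deposited table. FASLG (0.648 to 0.237 TPM, log2 -1.24 ± 0.67), TNF (0.307 to 0.303 TPM, log2 0.22 ± 0.64) and BAX (35.9 to 36.8 TPM, log2 0.24 ± 0.20) were not called in the authors' deposited table. TNFRSF1A was not called (106 to 95.4 TPM, log2 -0.06 ± 0.17 in the authors' deposited table), and its sign was positive on the TPM scale without the mitochondrially encoded genes.

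Over all entries 14.5% were called. Of the death receptor and necroptosis genes 2 of 22 were higher and 1 lower, and 2 and 1 when adjusted over the list alone. Of the mitochondrial apoptosis effectors 1 of 20 were higher and 2 lower, and 1 and 3 when adjusted over the list alone. Of 19 apoptosis inhibitors 1 was higher, and 0 when adjusted over the list alone, with 2 higher and 5 lower at an unadjusted p under 0.05 of the authors' Wald test. The medians of these lists were 0.00, 0.06 and 0.08, and -0.22, -0.15 and -0.14 on the TPM scale. Their means were -0.10, -0.09 and -0.10, while cameraPR placed all 3 on the side of rises relative to other genes. It called none of these lists (adjusted p = 0.936, 0.961 and 0.855).

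**Figure D3:**
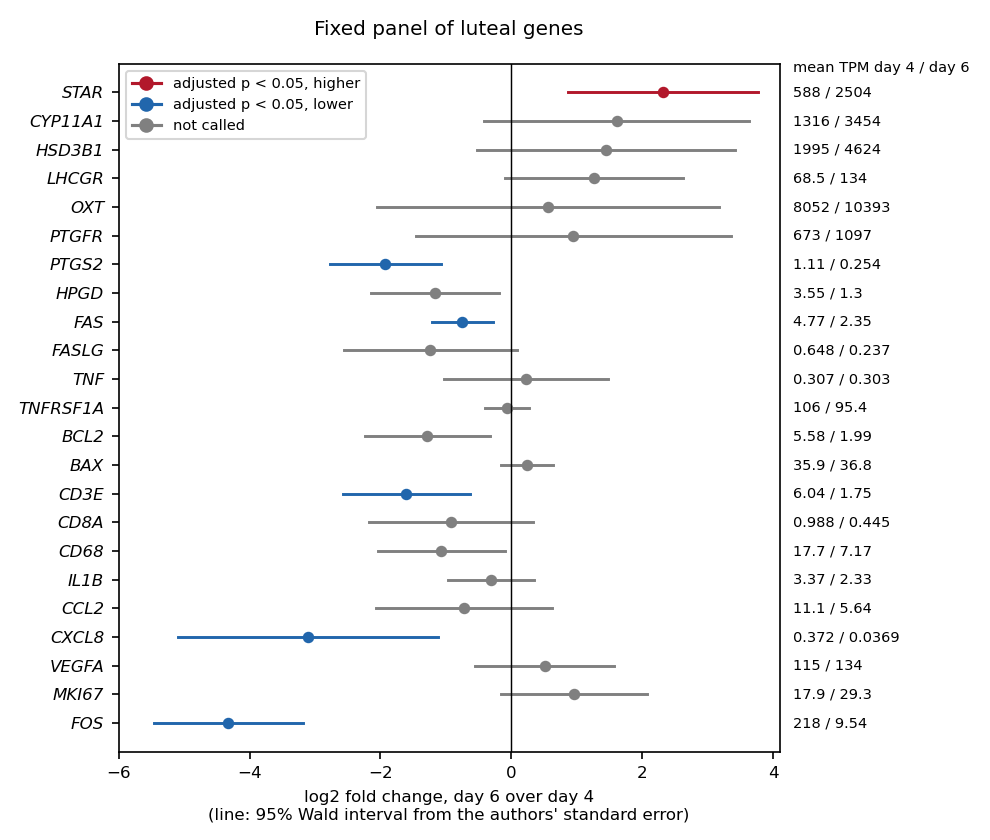
Log2 fold change (day 6 over day 4) of 23 of the 24 genes of a panel fixed before the data were examined, with the 95% Wald interval from the authors' standard error and the authors' mean TPM of each day at the right. STAR was called higher and PTGS2, FAS, CD3E, CXCL8 and FOS lower, and the sign of TNFRSF1A changes with the scaling.

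The T cell, natural killer cell and B cell lists each fell as a list. Many members were scarce: in that order 9 of 28, 11 of 23 and 8 of 20 averaged at least 1 TPM. Random lists matched on expression had negative medians too, of -0.40, -0.36 and -0.39. The medians of these lists lay at percentiles 0.11, 0.35 and 0.25 of the random ones. CD3E, a chain of the T cell receptor complex (6.04 to 1.75 TPM, log2 -1.60 ± 0.50, adjusted p = 0.015), and IL7R, the interleukin 7 receptor (1.31 to 0.225 TPM, log2 -2.32 ± 0.43, adjusted p = 7.64e-06), fell in the authors' deposited table. CD27 (9.35 to 4.25 TPM, log2 -0.95 ± 0.24), CD247 (4.08 to 1.41 TPM, log2 -1.33 ± 0.41) and BCL11B (0.212 to 0.0319 TPM, log2 -2.50 ± 0.77) fell there too, while CD8A was not called (0.988 to 0.445 TPM, log2 -0.93 ± 0.64). Of the T cell genes 7 of 28 were lower, and 10 when adjusted over the list alone, with a median of -1.27 (-1.41 to -0.94), with cameraPR adjusted p = 0.000282, or adjusted p = 0.0857 at the preset correlation of 0.1. Among natural killer and cytotoxic genes CTSW (7.29 to 0.985 TPM, log2 -2.67 ± 0.69, adjusted p = 0.00233) and PRF1, perforin (2.07 to 0.557 TPM, log2 -1.69 ± 0.47), fell in the authors' deposited table, with GNLY (4.49 to 1.2 TPM, log2 -1.60 ± 0.45) and NKG7 (4.88 to 1.84 TPM, log2 -1.16 ± 0.42). Of that list 4 of 23 were lower, and 4 when adjusted over the list alone, with a median of -1.24 (-1.60 to -0.56), with cameraPR adjusted p = 0.00548, or adjusted p = 0.147 at the preset correlation of 0.1. JCHAIN, the joining chain of secreted antibodies (66.8 to 2.2 TPM, log2 -4.78 ± 0.75, adjusted p = 4.85e-08), POU2AF1 (2.12 to 0.0306 TPM, log2 -5.60 ± 1.08), DERL3 (7.68 to 1.32 TPM, log2 -2.39 ± 0.62) and MZB1 fell in the authors' deposited table. Of the B cell and plasma cell genes 6 of 20 were lower, and 8 when adjusted over the list alone, with a median of -1.46 (-2.33 to -0.48), with cameraPR adjusted p = 0.000171, or adjusted p = 0.0609 at the preset correlation of 0.1.

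Macrophage and monocyte markers fell as a list. FCER1G (41.4 to 15.3 TPM, log2 -1.23 ± 0.25, adjusted p = 4.69e-05) and TYROBP (18.2 to 5.16 TPM, log2 -1.70 ± 0.39), adaptors of activating receptors, fell in the authors' deposited table, as did the Fc receptor FCGR2B (1.67 to 0.408 TPM, log2 -2.09 ± 0.49). LYVE1, also a lymphatic marker, rose (29.4 to 56.2 TPM, log2 1.16 ± 0.16, adjusted p = 1.22e-09), and CD68 was not called (17.7 to 7.17 TPM, log2 -1.07 ± 0.49), in the authors' deposited table. Of this list 1 of 28 were higher and 9 lower, and 1 and 14 when adjusted over the list alone, with a median of -0.99 (-1.17 to -0.72), with cameraPR adjusted p = 7.6e-05, or adjusted p = 0.0609 at the preset correlation of 0.1. Neutrophil markers were not called as a list. TREM1 (4.05 to 5.79 TPM, log2 0.75 ± 0.22, adjusted p = 0.01) and S100A8 (1.98 to 10.6 TPM, log2 2.60 ± 0.82, adjusted p = 0.0175) rose in the authors' deposited table. Of the neutrophil genes 2 of 20 were higher, and 2 when adjusted over the list alone. The neutrophil median was 0.12 (-0.13 to 0.72), with cameraPR adjusted p = 0.547, and -0.10 on the TPM scale. Among mast cell and eosinophil genes IL1RL1 (0.458 to 0.0523 TPM, log2 -2.97 ± 0.89) and GATA2 (6.09 to 3.12 TPM, log2 -0.73 ± 0.27) fell in the authors' deposited table, while FCER1A (2.05 to 0.45 TPM, log2 -2.08 ± 0.78) and KIT (38.4 to 64.9 TPM, log2 1.01 ± 0.42) were not called. Of that list 2 of 14 were lower, and 3 when adjusted over the list alone, with a median of -1.22 (-2.29 to 0.25), with cameraPR adjusted p = 0.47.

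Antigen presentation genes of class I were called higher as a list by cameraPR at the preset correlation of 0.01. Their median, however, lay at percentile 66.7 of random lists matched on expression, whose own median was 0.14. PSMB9, a subunit of the immunoproteasome (43 to 127 TPM, log2 1.80 ± 0.35, adjusted p = 2.19e-05), and TAP1, of the peptide transporter (15.7 to 33.5 TPM, log2 1.32 ± 0.23, adjusted p = 1.57e-06), rose in the authors' deposited table, as did TAPBP (71.2 to 83.3 TPM, log2 0.44 ± 0.13) and ERAP1 (12 to 18.7 TPM, log2 0.87 ± 0.27). The transcription factor IRF1 was the only member called lower (14.8 to 6.26 TPM, log2 -1.03 ± 0.34 in the authors' deposited table). Of the class I genes 4 of 23 were higher and 1 lower, and 4 and 1 when adjusted over the list alone. The class I median was 0.20 (0.02 to 0.34), with cameraPR adjusted p = 0.0338, or adjusted p = 0.143 at the preset correlation of 0.05, and it was -0.02 on the TPM scale. The class I call was also lost on that scale, on ranks of the score and with a minimum mean of 1 TPM. CD74, the invariant chain of class II, fell (404 to 156 TPM, log2 -1.19 ± 0.37, adjusted p = 0.0165) in the authors' deposited table. BOLA-DMB (15.4 to 8.31 TPM, log2 -0.68 ± 0.26), BOLA-DRA (63.9 to 33.3 TPM, log2 -0.74 ± 0.28) and LGMN (91.6 to 59.9 TPM, log2 -0.40 ± 0.15) were not called there. Of the class II genes 1 of 18 were lower, and 5 when adjusted over the list alone, with a median of -0.41 (-0.71 to -0.09), with cameraPR adjusted p = 0.101. The class II genes BOLA-DRB3, BOLA-DRB2, BOLA-DQA1 and BOLA-DQA2 were not matched, so the list result does not cover them. Interferon-stimulated genes rose as a list, with a median of 0.34 (0.06 to 0.67), with cameraPR adjusted p = 0.0104, or adjusted p = 0.111 at the preset correlation of 0.05. EIF2AK2, a sensor of double-stranded RNA, rose (11.8 to 23.9 TPM, log2 1.26 ± 0.38, adjusted p = 0.0119) and GBP5 fell (4.56 to 1.37 TPM, log2 -1.48 ± 0.46, adjusted p = 0.0154) in the authors' deposited table, where IFIT3 (3.02 to 1.75 TPM, log2 -0.54 ± 0.20) and IFI27 (45.7 to 118 TPM, log2 1.59 ± 0.62) were not called. Of the interferon-stimulated genes 1 of 37 were higher and 1 lower, and 1 and 1 when adjusted over the list alone.

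Cytokine and chemokine genes fell as a list. CXCL12, a chemokine of stromal cells (285 to 34.6 TPM, log2 -2.71 ± 0.57, adjusted p = 9.94e-05), and IL6 (2.26 to 0.201 TPM, log2 -3.33 ± 0.66, adjusted p = 2.74e-05) fell in the authors' deposited table. IL34, a ligand of the macrophage growth factor receptor (11.2 to 3.05 TPM, log2 -1.73 ± 0.38), IL16 (2.56 to 0.54 TPM, log2 -2.14 ± 0.52) and CXCL8, which attracts neutrophils (0.372 to 0.0369 TPM, log2 -3.11 ± 1.01, adjusted p = 0.0219), fell there as well. IL1B (3.37 to 2.33 TPM, log2 -0.31 ± 0.34) and CCL2 (11.1 to 5.64 TPM, log2 -0.72 ± 0.69) were not called in the authors' deposited table. Of these genes 13 of 48 were lower, and 14 when adjusted over the list alone, with a median of -1.01 (-1.48 to -0.54), with cameraPR adjusted p = 0.000171, or adjusted p = 0.116 at the preset correlation of 0.1. Complement genes fell as a list. The regulator SERPING1, the C1 inhibitor (329 to 27.4 TPM, log2 -3.42 ± 0.61, adjusted p = 2.78e-06), fell in the authors' deposited table, as did the activator CFD (40.5 to 7.28 TPM, log2 -2.31 ± 0.46) and the receptor C5AR1 (4.45 to 1.41 TPM, log2 -1.42 ± 0.29). Of the complement genes 2 of 31 were higher and 13 lower, and 4 and 15 when adjusted over the list alone, with a median of -0.78 (-1.28 to -0.25), with cameraPR adjusted p = 0.00116, or adjusted p = 0.123 at the preset correlation of 0.1.

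Pericyte and smooth muscle markers fell as a list. MYH11, smooth muscle myosin (244 to 11.3 TPM, log2 -4.25 ± 0.65, adjusted p = 2.63e-08), and DES, desmin (52.8 to 3.55 TPM, log2 -3.68 ± 0.33, adjusted p = 1.55e-24), fell in the authors' deposited table, as did LMOD1 (30.6 to 2.62 TPM, log2 -3.35 ± 0.55) and the signalling regulator RGS4 (13.9 to 1.01 TPM, log2 -3.60 ± 0.45). Named after their values were seen, the pericyte genes RGS5 (133 to 116 TPM, log2 0.05 ± 0.30) and MCAM (56.6 to 52.3 TPM, log2 0.11 ± 0.20) were not called in the authors' deposited table, and both were negative on the TPM scale. KCNJ8, a potassium channel of pericytes and the only member called higher, stood at 11.4 to 14.3 TPM, log2 0.56 ± 0.20 there. Of the pericyte and smooth muscle genes 1 of 22 were higher and 11 lower, and 1 and 11 when adjusted over the list alone, with a median of -0.87 (-1.84 to -0.03), with cameraPR adjusted p = 2.29e-07, or adjusted p = 0.00698 at the preset correlation of 0.1. Fibroblast markers fell as a list. GSN, gelsolin (1059 to 132 TPM, log2 -2.83 ± 0.56, adjusted p = 3.25e-05), and the growth factor receptor PDGFRA (151 to 34.8 TPM, log2 -1.95 ± 0.42, adjusted p = 0.00013) fell in the authors' deposited table, with the matrix genes FBLN1 (716 to 164 TPM, log2 -2.07 ± 0.45) and DCN, decorin (1106 to 358 TPM, log2 -1.43 ± 0.31). Of the fibroblast genes 0 of 21 were higher and 8 lower, and 1 and 9 when adjusted over the list alone, with a median of -0.59 (-1.43 to -0.04), with cameraPR adjusted p = 0.00158, or adjusted p = 0.109 at the preset correlation of 0.1.

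The structural matrix was not called as a list. COL12A1 fell (186 to 61.8 TPM, log2 -1.37 ± 0.36) with FBLN1 and DCN, and HSPG2, the basement membrane proteoglycan perlecan, rose (71.4 to 102 TPM, log2 0.75 ± 0.19), in the authors' deposited table. Of the matrix genes 1 of 37 were higher and 8 lower, and 2 and 8 when adjusted over the list alone. The median was 0.00, and -0.22 on the TPM scale (cameraPR adjusted p = 0.689). Among matrix proteases and their inhibitors ADAMTS10 fell in the authors' deposited table (24.1 to 4.86 TPM, log2 -2.13 ± 0.41). ADAMTS1 (90.9 to 25.6 TPM, log2 -1.62 ± 0.35) and MMP2, a gelatinase (459.9 to 178 TPM, log2 -1.18 ± 0.29), fell there too. Named after their values were seen, the inhibitor TIMP2 (1544 to 3968 TPM, log2 1.60 ± 0.40) and MMP7, matrilysin (0.0113 to 0.566 TPM, log2 5.78 ± 1.49), rose in the authors' deposited table. Of the protease list 6 of 34 were higher and 10 lower, and 6 and 13 when adjusted over the list alone, with a median of -0.54 (-0.73 to 0.26), with cameraPR adjusted p = 0.164, and a mean of -0.03.

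Angiogenic factors and receptors fell as a list. THBS1, a thrombospondin that restrains vessel growth (231 to 66.1 TPM, log2 -1.60 ± 0.28, adjusted p = 1.78e-06), and ANGPT2, a destabilizer of vessels (19.7 to 6.23 TPM, log2 -1.91 ± 0.44), fell in the authors' deposited table. The receptors NRP2 (53.1 to 13.4 TPM, log2 -1.78 ± 0.36) and S1PR1 (24.6 to 9.5 TPM, log2 -1.17 ± 0.28) fell there too. VEGFA, an endothelial growth factor, was not called (115 to 134 TPM, log2 0.51 ± 0.54, adjusted p = 0.57 in the authors' deposited table). Of these genes 1 of 33 were higher and 12 lower, and 1 and 15 when adjusted over the list alone, with a median of -0.46 (-1.11 to -0.09), with cameraPR adjusted p = 0.00177, or adjusted p = 0.147 at the preset correlation of 0.1. Endothelial markers did not pass as a list. ACKR1, of venules (2.77 to 0.122 TPM, log2 -4.32 ± 0.73, adjusted p = 4.73e-07), and CLDN5, of tight junctions (60.1 to 15.6 TPM, log2 -1.75 ± 0.46), fell in the authors' deposited table, with SELP (4.89 to 1.64 TPM, log2 -1.40 ± 0.44) and EGFL7 (86 to 50.4 TPM, log2 -0.56 ± 0.19). Of the endothelial genes 5 of 27 were lower, and 5 when adjusted over the list alone, with a median of -0.22 (-0.46 to 0.08), with cameraPR adjusted p = 0.277. Of the lymphatic markers 1 of 10 were higher and 3 lower, and 1 and 4 when adjusted over the list alone, with a median of -0.94 (-1.97 to 0.82), with cameraPR adjusted p = 0.629. TBX1 (5.7 to 0.71 TPM, log2 -2.86 ± 0.76), MMRN1 (13.2 to 1.8 TPM, log2 -2.74 ± 0.76) and RELN (2.67 to 0.749 TPM, log2 -1.66 ± 0.54) fell in the authors' deposited table.

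Immediate early genes, which respond within minutes to signals and to tissue handling, fell as a list. FOS (218 to 9.54 TPM, log2 -4.32 ± 0.58, adjusted p = 1.16e-10), CCN1 (337 to 27.1 TPM, log2 -3.44 ± 0.37, adjusted p = 1.76e-17), JUN (182 to 18.3 TPM, log2 -3.10 ± 0.47) and DUSP1 (145 to 37.9 TPM, log2 -1.74 ± 0.29) fell in the authors' deposited table. Of this list 1 of 32 were higher and 21 lower, and 1 and 23 when adjusted over the list alone, with a median of -1.13 (-1.64 to -0.75), with cameraPR adjusted p = 3.03e-13, or adjusted p = 0.000421 at the preset correlation of 0.1. Heat shock genes went both ways. HSPA1A, the inducible chaperone (292 to 39.1 TPM, log2 -2.69 ± 0.35, adjusted p = 7.93e-12), and HSPB8 (14.1 to 5.33 TPM, log2 -1.20 ± 0.42) fell in the authors' deposited table, and HSP90AA1 (491 to 658 TPM, log2 0.53 ± 0.18) and the mitochondrial HSPA9 (119 to 188 TPM, log2 0.88 ± 0.31) rose. Of the heat shock genes 2 of 22 were higher and 2 lower, and 5 and 5 when adjusted over the list alone, with a median of 0.22 (-0.26 to 0.45), with cameraPR adjusted p = 0.652, and a mean of -0.10. Among hypoxia response genes NDRG1 (30.5 to 8.33 TPM, log2 -1.78 ± 0.31, adjusted p = 8.08e-07), PPP1R3C (12.4 to 1.95 TPM, log2 -2.46 ± 0.45) and ANKRD37 (2.46 to 0.218 TPM, log2 -3.27 ± 0.66) fell and CA9, a carbonic anhydrase, rose (1.88 to 3.93 TPM, log2 1.29 ± 0.26) in the authors' deposited table. Of the hypoxia genes 1 of 28 were higher and 6 lower, and 1 and 8 when adjusted over the list alone. Their median was -0.03 (-0.40 to 0.28), with cameraPR adjusted p = 0.365, and 0.10 on the TPM scale without the mitochondrially encoded genes. Among genes of endoplasmic reticulum stress the transcription factors DDIT3 (36.8 to 19 TPM, log2 -0.85 ± 0.22, adjusted p = 0.00282) and ATF4 (283 to 170.1 TPM, log2 -0.53 ± 0.18) fell in the authors' deposited table, and ATF6 (21.1 to 28.9 TPM, log2 0.65 ± 0.24) and SEL1L (26.8 to 29.3 TPM, log2 0.35 ± 0.13) rose. Of that list 2 of 28 were higher and 2 lower, and 2 and 2 when adjusted over the list alone. The stress list median was 0.20 (0.09 to 0.33), with cameraPR adjusted p = 0.0952, and -0.02 on the TPM scale. On ranks of the score the stress list passed as higher (adjusted p = 0.0428).

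Markers of epithelium of the ovarian surface or oviduct, of adipocytes, and of erythrocytes and platelets were not called as lists at the preset correlation of 0.01. The epithelial genes WT1 (34.6 to 6.94 TPM, log2 -2.17 ± 0.44, adjusted p = 5.16e-05) and OVGP1 (1.59 to 0.262 TPM, log2 -2.40 ± 0.51) fell and KRT19 was not called (0.929 to 0.296 TPM, log2 -1.45 ± 0.58) in the authors' deposited table. LRRN4, listed there at 0 on day 6, was not called. Of the epithelial genes 2 of 16 were lower, and 2 when adjusted over the list alone, with a median of -0.48 (-2.08 to 0.03), with cameraPR adjusted p = 0.0943. The adipocyte genes LPL (86.4 to 26.3 TPM, log2 -1.51 ± 0.33), GPD1 (7.95 to 2.55 TPM, log2 -1.45 ± 0.39) and PPARG (3.04 to 1.08 TPM, log2 -1.32 ± 0.36) fell and AGPAT2 was not called (6.73 to 3.04 TPM, log2 -0.96 ± 0.39) in the authors' deposited table. Of the adipocyte genes 3 of 12 were lower, and 4 when adjusted over the list alone, with a median of -0.79 (-1.28 to -0.02), with cameraPR adjusted p = 0.092. Of 14 erythrocyte and platelet genes GYPC fell (87.9 to 41.6 TPM, log2 -0.87 ± 0.31), while ITGA2B (3.81 to 2.33 TPM, log2 -0.49 ± 0.27), HBB (0.369 to 0.851 TPM, log2 1.38 ± 0.95) and ALAS2 (0.0208 to 0.08 TPM, log2 2.13 ± 1.62) were not called, in the authors' deposited table. HBA, a haemoglobin gene whose p-value is deposited as 1 and which is given after its values were seen, stood at 15.1 to 3.56 TPM, log2 -1.99 ± 0.89 in the authors' deposited table. Adjusted over the list alone 0 of these were called, with 0 higher and 1 lower at an unadjusted p under 0.05 of the authors' Wald test. Their median was -0.37 (-0.87 to 0.69), with cameraPR adjusted p = 0.961, and the mean was 0.03. With a minimum mean of 1 TPM the protease and adipocyte lists passed as lower (adjusted p = 0.019 and 0.0109).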

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

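All alternatives here were chosen after the data were examined, since those fixed beforehand need values per library. The count of genes differing kept within 1.5 times its value of 2823 under the other scalings and the minimum of 1 TPM (2539 to 4128). The genes shared with it numbered 2319 on the TPM scale, 2398 on the TPM scale without the mitochondrially encoded genes, 2674 after centring and 2383 with a minimum of 1 TPM. The split by direction moved: 299 were higher and 3829 lower on the TPM scale, and 1848 were higher without the mitochondrially encoded genes. The alternative moves every gene by the same amount, which by construction shifts calls from one side to the other. At an adjusted p under 0.01 there were 1443 genes (301 higher, 1142 lower), and against a fold of 1.5 there were 502 (45 higher, 457 lower), both stricter by construction. With a t distribution of 5 degrees of freedom 0 were called (0 higher, 0 lower), the smallest adjusted p was 0.245, and 3133 had an unadjusted p under 0.05. That distribution ignores the sharing of spread between genes in the authors' test and is the strictest alternative run. Of the 187 named genes (140 called) 14 lost their call on the TPM scale and 17 gained one, 7 lost and 7 gained one without the mitochondrially encoded genes, 42 lost it at an adjusted p under 0.01, 87 against a fold of 1.5 and all 140 with the t distribution. The log2 fold change of TNFRSF1A became 0.0654 on the TPM scale without the mitochondrially encoded genes.

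Of the fixed lists 15 were called at a preset correlation of 0.05 and 2 at 0.1, against 17. On ranks of the score 17 were called, 16 of them shared, on the TPM scale 16, all shared, and with a minimum of 1 TPM 18, of which 16 were shared. Lists that were not called changed side on the TPM scale: death receptor apoptosis (adjusted p = 0.869), mitochondrial apoptosis effectors (0.858), apoptosis inhibitors (0.801), PGF2α receptor signalling (0.904) and erythrocytes (0.586). So did death receptor apoptosis on ranks (adjusted p = 0.916) and mitochondrial apoptosis effectors with a minimum of 1 TPM (0.885). The cause was not tested.

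No paired analysis was possible because the deposited table holds group means and no values per library. For the same reason these alternatives, fixed before the data were examined, were not run: other count scalings and count filters, other count models, other pseudocounts, leaving out the most abundant genes or each library in turn, a replicate block, an estimated correlation between genes and the fry test. Other splits of the libraries, their similarity and outlying libraries were not examined, for want of the same values. The depth is unknown. Simulated changes of 1 on the log2 scale were recovered in 35% of genes, with 200 of 19485 genes changed. With the 2823 calls of the authors' test the adjusted cut-off is less strict. The share of such changes left uncalled there is therefore not known.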

Other observations

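All tests in this part were chosen after the results were seen, as were the genes named in it, except the ribosomal protein examples, HBB and ATP8, which follow the naming rule. Genes of cytoplasmic ribosomal proteins fell together. Of 73 tested, 59 were called lower, and 72 when adjusted over the list alone, and the median was -0.78 (-0.86 to -0.73), with cameraPR adjusted p = 9.14e-22, or adjusted p = 0.000113 at the preset correlation of 0.1. RPS12 (4198 to 1872 TPM, log2 -0.96 ± 0.25, adjusted p = 0.00214), RPS15A (1237 to 626 TPM, log2 -0.77 ± 0.18), RPS23 (1463 to 638 TPM, log2 -0.99 ± 0.25) and RPL35A (2437 to 958 TPM, log2 -1.14 ± 0.28) fell in the authors' deposited table. The list median was lower still on the TPM scale, and -0.65 on the TPM scale without the mitochondrially encoded genes. EEF1A1, a translation elongation factor (5927 to 3441 TPM, log2 -0.60 ± 0.27, adjusted p = 0.123), and TPT1 (4415 to 2568 TPM, log2 -0.57 ± 0.22, adjusted p = 0.0521), whose messages start with an oligopyrimidine tract as those of ribosomal proteins do, were not called in the authors' deposited table.

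Other genes with large changes, picked by eye, belong to no tested list. FASN, fatty acid synthase (51.9 to 132 TPM, log2 1.60 ± 0.47, adjusted p = 0.0097), ACLY, which supplies it with acetyl groups (101 to 256 TPM, log2 1.61 ± 0.59), and FADS6 (15.1 to 55.8 TPM, log2 2.12 ± 0.49) rose in the authors' deposited table. BCAT2, a mitochondrial transaminase of branched amino acids (81 to 273 TPM, log2 1.98 ± 0.56), TF, transferrin (13.7 to 45.7 TPM, log2 1.97 ± 0.52), CA2, a carbonic anhydrase (43.5 to 161 TPM, log2 2.16 ± 0.65), and AVPR1A, a vasopressin receptor (0.168 to 1.88 TPM, log2 3.69 ± 0.54), rose there too. Among other falls were the elastic fibre genes MFAP4 (362 to 8.21 TPM, log2 -5.33 ± 1.11, adjusted p = 8.77e-05) and LTBP4 (152 to 6.26 TPM, log2 -4.42 ± 0.66) in the authors' deposited table. APOD, apolipoprotein D (641 to 53.3 TPM, log2 -3.41 ± 0.72), MUSTN1 (301 to 5.25 TPM, log2 -5.69 ± 0.74), NUPR1 (308 to 14.7 TPM, log2 -4.21 ± 0.63) and IGSF10 (6.63 to 0.253 TPM, log2 -4.53 ± 0.42) fell there as well.

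Transcripts of T cells, B cells, macrophages and smooth muscle were lower on day 6. Dilution by luteal cell RNA of every other cell type alike would lower endothelial genes as much. The endothelial median lay 0.52 (0.23 to 0.84) above that of the 4 lists, each relative to genes of like expression. That goes against such dilution, but the 4 lists were chosen after their fall was seen, and the interval covers genes and not animals. Dilution therefore stays open. More blood in the day 4 tissue stays open: the neutrophil median lay 1.38 (0.89 to 1.79) above that of T cells, which goes against it, but both lists were scarce (median 0.931 and 0.91 TPM on day 4), and the haemoglobin genes go apart. HBA goes with more blood (15.1 to 3.56 TPM, log2 -1.99 ± 0.89, deposited without a valid p-value), and the scarcer HBB does not (0.369 to 0.851 TPM, log2 1.38 ± 0.95, not called), in the authors' deposited table. Ovarian tissue taken along on day 4 cannot be told apart from the day, since the fibroblast median of -0.59 goes with both. So do the medians of the adipocyte (-0.79) and epithelial (-0.48) lists, which were not called. A lower number of T cells, B cells, macrophages and smooth muscle cells in the gland on day 6 stays open and untested.

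Mitochondrially encoded transcripts were higher on day 6. Scaling between libraries as the whole cause is argued against for the scales run. The lowest of the 13 fold changes was still 0.89 (95% interval from 0.52) on the TPM scale, the one most against it. All of these scales are relative, so a loss of other transcripts cannot be told apart from this rise. Shared reads of overlapping genes are argued against, since the lowest fold change among 6 genes with no overlapping neighbour, that of ND3, was 1.11 (from 0.74). The median of 1.81 cannot be told apart from a change of collection route or handling before freezing, because the labels give no day that was collected both ways. A biological rise with luteal age, as the design names it, stays open and untested.

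Immediate early gene transcripts were lower on day 6. Their median of -1.13 cannot be told apart from a change of collection route or handling, because the labels give no day that was collected both ways. Fewer immune and smooth muscle cells may account for it: relative to genes of like expression the list lay -0.11 (-1.16 to 0.99) from pericytes and smooth muscle, the lowest of the 4 lists on that measure, and -0.22 (-1.21 to 0.87) from B cells and plasma cells, the lowest by log2 fold change, intervals that decide nothing. An effect of the day itself stays open and untested.

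A total of 54 entries of the authors' deposited table have a p-value of 1, and 33 of the 51 with a score lie beyond the normal 95% limit of 1.96 in size. One is KCNK3, a potassium channel, at 26 to 83.4 TPM in the authors' deposited table. The deposited columns list 544 entries at 0 on day 4 and 751 on day 6. ATP8 alone held 4.65% of the authors' mean TPM on day 4 and 14.1% on day 6.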
